A study of Glycine max with 72 samples.

How the data were processed

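The series measured mRNA in soybean leaves on 72 Affymetrix Soybean Genome Arrays, 1 array per sample. Per the labels, total RNA was extracted with a QIAGEN plant kit and labelled with biotin. The deposited values are intensity values on a linear scale, 1 per probe set, made by the authors with MAS5 per the submitters' processing notes, and its version is not given in the sources used here. The mean of each array's values with 2% trimmed at each end lay between 500.1 and 500.2, so that all arrays had been brought to a common mean before deposit. No detection calls were used. The number of arrays limits the precision, and a signal near background has a fold change that depends on the pseudocount.

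Groups came from the sample titles, which give genotype, inoculation, time and replicate for each array. They form 24 groups of 3 arrays: 2 genotypes, mock or inoculated, at 6 times. The germplasm tag names Williams on every sample and the isolate tag conflicts with the descriptions for Williams, so neither tag was used. Nothing in the labels says whether replicates came from separate plants, so p-values measure only the spread between these arrays, which may be technical in part. Deviations from the group means of mock and inoculated arrays with the same replicate number correlated over 0.1 in all 3 pairs for PI459025B at 72 hai (0.225, 0.159 and 0.433) and in no other comparison, a hint from the data and not the labels. No 2 arrays held identical values. Correlations of log2 values between arrays of a group lay between 0.833 and 0.981.

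Values were used as log2(value + 16), without further scaling. A fold change on this scale understates the change of weak genes. The table held 37593 soybean probe sets. A probe set was kept when it lay above the 20th percentile of its array in at least 3 of the 72 arrays, which left 36352. This percentile is called the background threshold in the report. This is the fallback rule written for a table without Phytophthora or Heterodera probe sets, of which it holds 0. Control probe sets stayed out of the tests and served as measures of array quality.

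Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 72 arrays in 1 fit and no block. The fit had 48 residual and 5.34 prior degrees of freedom. There were 19 comparisons: inoculated against mock for each genotype and time, the difference of these responses between genotypes at each time, and the genotypes in mock leaves over all times. P-values were adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at an adjusted p under 0.05. The designs, gene lists and main alternatives were fixed before the data were examined.

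Probe sets took their names from the platform annotation, updated through the RefSeq gene table of assembly Glycine_max_v4.0, used for names only. A single gene symbol was found for 8677 probe sets, several for 370 and none for 28546 soybean probe sets. Of the first, 8652 were found in the RefSeq table, and 1882 had a symbol or synonym that was not a placeholder. No gene descriptions were used, so lists rest on symbols and synonyms.

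Named genes followed a rule. Among called probe sets with a gene symbol, with all 3 arrays of 1 group beyond all 3 of the other, the 3 with the largest change in each direction were taken per genotype and time, 1 probe set per gene. For differences between genotypes the top 2 in each direction were taken, and for mock leaves the top 10, without the condition of separated arrays. The rule was applied as written, with placeholder symbols counted, and again to genes with a symbol or synonym that is not a placeholder. The second use was added once the annotation had been seen and before any test was run, and most genes named come from it. Members of a list were named by smallest p.

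Of the lists of genes, 19 had at least 5 kept probe sets and were tested with limma's camera at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusting over all lists and 18 comparisons. Chitinases and glucanases (2 probe sets), circadian clock (4) and histones (2) were too small, and the lists for lignin, NBS-LRR proteins, epidermis and vascular tissue had 0 members. Several probe sets of a list can measure 1 gene, and the counts given are of probe sets. The isoflavonoid list covered 25 genes, WRKY 53, glutathione S-transferases 37, cytochrome P450 44 and jasmonate 15. Heat shock covered 5 genes, pathogenesis-related, ribosomal, peroxidase and senescence 4 each, and photosynthesis 3. The preset correlation of 0.01 makes little allowance for probe sets of 1 gene that move together. The cytochrome P450 list held 16 probe sets whose symbols read as cyclophilins, and the root and nodule list 1 outside its name. An alternative without them was added after seeing the annotation.

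The fit was tested on simulated data with the mock group means and the fitted spread of each of 36352 probe sets. For Williams inoculated versus mock at 144 hours, 35 of 100 probe sets changed 2-fold and 89 of 100 changed 4-fold were called, with 3 false calls among 127. For the difference between genotypes at 144 hours, 3 of 100 changed 2-fold and 58 of 100 changed 4-fold were called, with 3 false calls among 64. For the genotypes in mock leaves, 97 of 100 changed 2-fold and 100 of 100 changed 4-fold were called, with 7 false calls among 204. No called probe set had the wrong sign (0 in each case). Camera gave an unadjusted p = 3.83e-36 for a changed list, and 0 of 50 unchanged lists had a p under 0.05. The simulated noise was independent between probe sets and equal in spread on all arrays. These checks therefore do not show how calls hold with correlated genes or noisier arrays, as in the real data. Only 100 probe sets were changed at each size, against 3599 called in the real Williams comparison at 144 hours. The Benjamini-Hochberg cutoff depends on how many probe sets change, so the recovered shares do not carry over to the real comparisons.

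Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a filter at 12 arrays, a replicate block, a fit to only the arrays compared, array weights, a trended and robust eBayes, and leaving out each array in turn. After seeing the data, a fit was added without the 3 arrays whose mean hybridization-control signal was over 2 times the median of all arrays, as were contrasts of the response between consecutive times, the late response of ICL1 in PI459025B and fits of the array quality measures with arrays left out.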

Results

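Leaves of 2 soybean genotypes were profiled after mock treatment or inoculation with the rust isolate Hawaii 94-1. The lines were Williams and PI459025B, which is known as a source of the Rpp4 locus named in the series title. The arrays ask how each line's leaf mRNA responds over time and where the responses differ. Arrays were taken at 12, 24, 72, 144, 216 and 288 hours after inoculation (hai), with 3 arrays in each of 24 groups. Changes are log2 fold changes, each from 3 inoculated against 3 mock arrays, and calls are from limma with Benjamini-Hochberg adjustment over 36352 probe sets. Standard errors and p-values rest on a spread pooled over all 72 arrays in 1 fit, not on that of the arrays compared. In the Williams inoculated groups at 216 and 288 hai, arrays deviated from the group mean with a mean SD of 0.593 and 0.517. The median over all arrays was 0.340, so the errors given for those groups may be too small. Group signals are means ± SD of 3 arrays. Genes are named for a genotype by size of change, so a gene named for 1 line can have changed in the other too. The probe set named for a gene can differ between lines, times and contrasts, as for GSTU47, OLPa, PRX4, ICL1, VLXB and PR-10.

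The hybridization-control mean of the arrays had a median of 1860 and a lowest value of 1314, and some late inoculated arrays stood above the rest. Replicate 3 of Williams inoculated at 216 hai reached 11550, replicate 1 of Williams inoculated at 288 hai 4317, and replicate 2 of PI459025B inoculated at 288 hai 4279. The first also had a GAPDH 3' to middle ratio of 13.3 and an actin 3' to 5' ratio of 17.1. These 3 arrays are called the high-control arrays. Counts without them were computed after their values had been seen, and are given where they moved by over 1.5 times. The closest array lay in the same group for 54 of 72 arrays.

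**Figure D1:**
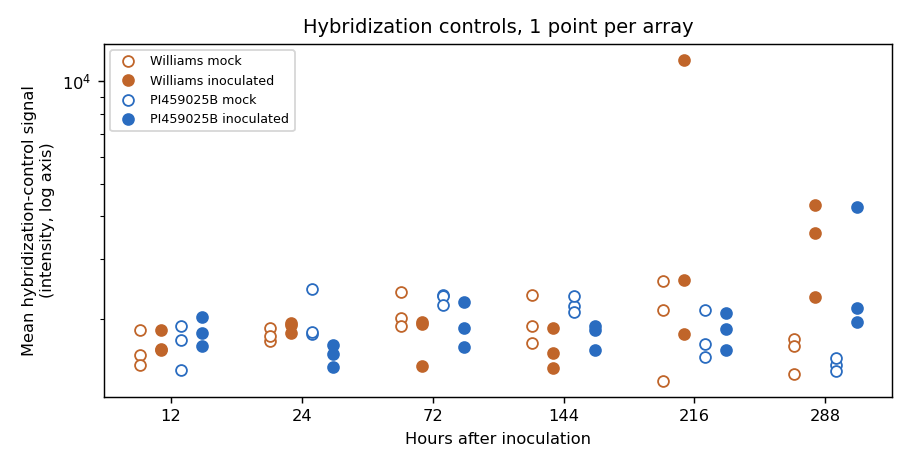
Mean hybridization-control signal (intensity, log axis) of each array against time, by genotype and inoculation. The highest point, 11550, is Williams inoculated at 216 hai, and the inoculated arrays at 288 hai reach 4317 in Williams and 4279 in PI459025B.

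At 12 hai, genes of phytoalexin synthesis rose in both genotypes. CYP93A1, a hydroxylase of glyceollin synthesis, rose by 5.85 ± 0.48 in Williams (adjusted p = 1.28e-13) and by 5.81 ± 0.48 in PI459025B (adjusted p = 1.63e-13). Its signal in Williams was 3700 ± 1522 against 44.7 ± 9.02 in mock leaves. The isoflavone methyltransferase gene iomt2 rose by 5.42 ± 0.74 and 5.58 ± 0.74. OLPa, an osmotin-like protein, rose by 5.53 ± 0.76 in Williams, and CYP71D8 rose by 6.13 ± 0.69 in PI459025B. Among genes that fell were MYB139 (-3.24 ± 0.60), COI1, the jasmonate receptor (-2.64 ± 0.51), and MYB173 (-2.56 ± 0.38) in Williams, and MYB149 (-2.65 ± 0.44), DD2/63 (-2.53 ± 0.52) and MYB139 (-2.24 ± 0.60) in PI459025B. MYB139 was at or below the background threshold in all 3 inoculated Williams arrays, so the size of its change depends on the pseudocount. In PI459025B its call was lost without inoculated replicate 2 (adjusted p = 0.118).

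Of 56 probe sets for isoflavonoid and glyceollin synthesis, 38 rose, 0 fell and 18 did not pass at 12 hai in Williams, and 36 rose and 20 did not pass in PI459025B. The counts adjusted over the list alone were also 38 and 36. Examples in Williams were G4DT, a prenyltransferase (4.82 ± 0.43), isoflavone synthase IFS1 (4.43 ± 0.41) and chalcone synthase CHS1 (3.55 ± 0.35). The list rose against other genes (camera adjusted p = 2.34e-31 and 5.02e-34; adjusted p = 0.00687 in both with an estimated correlation). Of 12 probe sets at the entry to phenylpropanoid synthesis, 10 rose in each genotype, and 10 when adjusted over the list alone. They included C4H, at 2.14 ± 0.24 in Williams and 2.20 ± 0.24 in PI459025B (camera adjusted p = 8.2e-16 and 1.23e-16; adjusted p = 0.0085 and 0.00687 with an estimated correlation). Of 17 heat shock probe sets, 7 rose in Williams and 13 in PI459025B (8 and 14 adjusted over the list alone), HSP90-1 by 1.78 ± 0.38 and 2.30 ± 0.38 (camera adjusted p = 9.73e-06 and 1.39e-10; adjusted p = 0.184 and 0.052 with an estimated correlation).

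In all, 7499 probe sets were called at 12 hai in Williams, 2767 higher and 4732 lower, and 6519 in PI459025B, 2876 higher and 3643 lower. The median over all probe sets was -0.19 in Williams and -0.17 in PI459025B. With median centring the split was 3901 higher and 2177 lower in Williams and 3250 higher and 2175 lower in PI459025B, and with quantile normalization 3252 higher and 3437 lower in Williams, so the majority of lower calls depends on the scaling. Without Williams inoculated replicate 3 the Williams count was 4868.

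At 24 hai, most called probe sets were higher in inoculated leaves of both genotypes. OLPa rose by 4.07 ± 0.76 in Williams (adjusted p = 0.00291) and by 4.07 ± 0.76 in PI459025B (adjusted p = 0.000562). The pathogenesis-related gene PR-10 rose by 3.50 ± 0.72 and the peroxidase PRX4 by 3.35 ± 0.68 in Williams. In PI459025B, CYP71D8 rose by 4.65 ± 0.69 and CHIA1, a chitinase, by 4.22 ± 0.77, and GASA14 fell (-2.37 ± 0.61). The Williams calls of OLPa, PR-10 and PRX4 were lost without mock replicate 2 (adjusted p = 0.0911, 0.116 and 0.146) and without inoculated replicate 2 (0.0823, 0.195 and 0.237), and that of PRX4 with only the arrays compared (0.213). The GASA14 call was lost with a pseudocount of 1 (adjusted p = 0.104), and without mock replicates 2 (0.149) or 3 (0.0877) or inoculated replicates 2 (0.236) or 3 (0.0946). Of 7 probe sets for pathogenesis-related proteins 1 rose in Williams and 4 in PI459025B, or 4 and 6 adjusted over the list alone (camera adjusted p = 4.76e-09 and 2.91e-11; adjusted p = 0.0366 and 0.0176 with an estimated correlation). Of the 56 isoflavonoid probe sets, 2 rose in Williams and 17 in PI459025B, or 28 and 30 adjusted over the list alone (camera adjusted p = 7.12e-24 and 1.82e-28; adjusted p = 0.0176 and 0.00945 with an estimated correlation).

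The calls at 24 hai numbered 162 in Williams, 160 higher and 2 lower, and 495 in PI459025B, 476 higher and 19 lower. The Williams count was 8 without inoculated replicate 2 and 49 with only the arrays compared. The PI459025B count was 250 without inoculated replicate 2. Between 12 and 24 hai, the response itself differed at 1104 probe sets in Williams and 1105 in PI459025B.

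At 72 hai, pathogenesis-related genes rose in PI459025B. PR-10 rose there by 6.24 ± 0.72 (adjusted p = 1.82e-08), to a signal of 8025 ± 236 against 90.9 ± 16.2 in mock leaves. CHIA1 rose by 5.78 ± 0.77 and the isoflavone reductase GmIFR by 5.28 ± 0.58. GASA22 (-1.70 ± 0.51) and XET1 (-1.50 ± 0.46) fell. A probe set of GSTU47 also fell (-1.65 ± 0.39), but 2 others of that gene rose. GASA22 lost its call with a pseudocount of 1 (adjusted p = 0.185), without mock replicates 1, 2 or 3 (0.0778, 0.0889 and 0.0723) and without inoculated replicates 2 or 3 (0.114 and 0.143). XET1 lost it with quantile normalization (adjusted p = 0.0536), with only the arrays compared (0.0636), without mock replicates 2 or 3 (0.123 and 0.204) and without inoculated replicates 1, 2 or 3 (0.137, 0.0849 and 0.0695). The fall of GSTU47 was not called without mock replicate 2 (adjusted p = 0.0538) or inoculated replicate 2 (0.0598). In Williams, MYB92 (2.28 ± 0.44), WRKY62 (1.96 ± 0.43) and WRKY19 (1.88 ± 0.40) rose. HSF-08 (-2.59 ± 0.54), GSTU47 at another probe set than in PI459025B (-2.52 ± 0.54) and HSP23.9 (-2.24 ± 0.52) fell. The last is a small heat shock protein, and of 17 heat shock probe sets in Williams 1 fell, or 10 adjusted over the list alone (camera adjusted p = 2.32e-15; adjusted p = 0.018 with an estimated correlation), and in PI459025B 0 passed either way (camera adjusted p = 0.774). HSF-08 and GSTU47 were at or below the background threshold in all 3 inoculated Williams arrays.

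The 6 genes named for Williams at 72 hai had adjusted p between 0.21 and 0.434 with only the arrays compared, and between 0.245 and 0.558 without inoculated replicate 1, so none was called. Without mock replicate 1, HSF-08 (adjusted p = 0.166), GSTU47 (0.261), HSP23.9 (0.281), WRKY62 (0.312) and WRKY19 (0.191) were not called, and without mock replicate 3, HSF-08 (0.0809), HSP23.9 (0.12), WRKY62 (0.161), WRKY19 (0.12) and MYB92 (0.208) were not. Without inoculated replicate 2 the calls of GSTU47 (adjusted p = 0.0842), HSP23.9 (0.17) and WRKY62 (0.132) were lost, without mock replicate 2 that of HSP23.9 (0.0518), and without inoculated replicate 3 that of HSF-08 (0.0504). HSP23.9 also lost its call with quantile normalization (adjusted p = 0.0654), median centring (0.0534) and a pseudocount of 1 (0.0862), GSTU47 with pseudocounts of 1 (0.0999) and 64 (0.0528), and WRKY62 with median centring (0.0588).

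Of 7 probe sets for pathogenesis-related proteins, 6 rose at 72 hai in PI459025B and 0 in Williams (7 and 2 adjusted over the list alone), with PR1-7 at 4.66 ± 0.60 and PR1-1 at 2.51 ± 0.53 in PI459025B (camera adjusted p = 2.48e-16 in PI459025B and 0.00151 in Williams; adjusted p = 0.00687 and 0.251 with an estimated correlation). Of 103 WRKY probe sets, 37 rose in PI459025B and 4 in Williams (51 and 31 adjusted over the list alone, with 3 lower in PI459025B when so adjusted), among them WRKY21 (4.75 ± 0.58) and WRKY6 (3.59 ± 0.47) in PI459025B. Camera gave an adjusted p = 2.75e-17 in PI459025B and 1.88e-18 in Williams (adjusted p = 0.0421 and 0.0366 with an estimated correlation). Of 9 probe sets for salicylic acid and EDS1 signalling, 4 rose in PI459025B (6 adjusted over the list alone), including EDS1-2 at 2.12 ± 0.34 and PAD4 at 1.73 ± 0.28 (camera adjusted p = 9.49e-06; adjusted p = 0.052 with an estimated correlation), and 0 in Williams either way (camera adjusted p = 0.102). Isoflavonoid probe sets rose at 27 of 56 in PI459025B and 0 in Williams (31 and 20 adjusted over the list alone, with 1 lower in PI459025B when so adjusted), with adjusted p = 3.11e-17 and 2.76e-09 from camera (adjusted p = 0.0457 and 0.152 with an estimated correlation).

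The calls at 72 hai numbered 2209 in PI459025B, 1917 higher and 292 lower, and 56 in Williams, 42 higher and 14 lower. With median centring the splits were 1501 higher and 684 lower in PI459025B and 15 higher and 14 lower in Williams. The Williams count rests on single arrays, with 1 without inoculated replicate 1, 281 without mock replicate 2, 0 with only the arrays compared, and 169 without the high-control arrays, which belong to other groups.

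At 144 hai, PTS1 rose in Williams by 5.35 ± 0.55 (adjusted p = 1.21e-09), CYP82A4 by 4.57 ± 0.61 and isocitrate lyase ICL1, an enzyme of the glyoxylate cycle, by 4.71 ± 1.11. The vegetative lipoxygenase gene VLXC (-3.78 ± 1.08), CYP93E1 (-3.01 ± 0.92) and SOY69 (-2.73 ± 0.61) fell. In PI459025B, PR-10 rose by 7.22 ± 0.72 (adjusted p = 1.39e-10), OLPa by 6.26 ± 0.73 and SGlu11 by 6.16 ± 0.69, and GmTIP2;3 (-2.37 ± 0.64), NES (-2.32 ± 0.51) and CYP74A1 (-2.09 ± 0.53) fell. In Williams the calls of VLXC and CYP93E1 were lost without mock replicate 1 (adjusted p = 0.105 and 0.118), mock replicate 2 (0.056 and 0.0642), inoculated replicate 2 (0.0714 and 0.102) or inoculated replicate 3 (0.123 and 0.152), and that of CYP93E1 with a pseudocount of 1 (0.0512). In PI459025B the call of GmTIP2;3 was lost without inoculated replicate 3 (adjusted p = 0.0932) and that of CYP74A1 without mock replicate 3 (0.0668).

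Isoflavonoid probe sets rose at 19 of 56 in Williams, with 1 lower, and at 30 in PI459025B at 144 hai (32 and 31 higher adjusted over the list alone, with 3 lower in Williams; camera adjusted p = 7.39e-12 and 6.73e-19; adjusted p = 0.111 and 0.0366 with an estimated correlation). Of 7 probe sets for pathogenesis-related proteins 6 rose in PI459025B and 3 in Williams (7 and 3 adjusted over the list alone; camera adjusted p = 8.82e-15 and 6.57e-05; adjusted p = 0.00687 and 0.148 with an estimated correlation). Glutathione S-transferases were higher at 21 of 58 probe sets and lower at 1 in PI459025B, and higher at 9 and lower at 4 in Williams (24 and 3, and 15 and 5, adjusted over the list alone), with GSTU26 up by 4.77 ± 0.52 and 3.80 ± 0.52 (camera adjusted p = 6.76e-07 and 0.00127; adjusted p = 0.111 and 0.3 with an estimated correlation). Ribosomal protein probe sets rose at 6 of 10 in PI459025B (8 adjusted over the list alone), RPL2 by 1.36 ± 0.25 (camera adjusted p = 1.96e-06; adjusted p = 0.112 with an estimated correlation), and at 0 in Williams either way (camera adjusted p = 0.0418; adjusted p = 0.534 with an estimated correlation; adjusted p = 0.0586 with median centring). In total 3599 probe sets were called in Williams, 1661 higher and 1938 lower, and 4462 in PI459025B, 3089 higher and 1373 lower. With median centring PI459025B had 2506 higher and 2303 lower. Without the high-control arrays the Williams count was 5415, and without inoculated replicate 3 it was 2108. The PI459025B count was 2648 without inoculated replicate 2.

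At 216 hai, VLXC fell in both genotypes. In Williams, it fell by 7.56 ± 1.08 on the log2 scale (adjusted p = 3.15e-07), from a mock signal of 9666 ± 5852 to 30.2 ± 9.63, and LOX9 (-6.44 ± 0.93) and CYP93E1 (-6.26 ± 0.92) fell as well. In PI459025B, VLXC (-5.31 ± 1.08), MYB139 (-4.80 ± 0.60) and SALI5-4A (-4.69 ± 0.87) fell, the last to at or below the background threshold in all 3 inoculated arrays. Genes that rose in Williams were ICL1 (7.56 ± 1.11), PGIP, an inhibitor of fungal polygalacturonases (5.94 ± 0.51), and the peroxidase Ep (5.81 ± 0.68). ICL1 rose in PI459025B too, by 5.77 ± 1.11 (limma adjusted p = 5.42e-05) to a signal of 13870 ± 5638, against 28700 ± 16310 in Williams, and by 3.86 without PI459025B mock replicate 2 (adjusted p = 0.00784). Those in PI459025B were OLPa (6.66 ± 0.72), PRX4 (6.36 ± 0.78) and PR1-1 (6.07 ± 0.53).

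Of 36 probe sets for jasmonate synthesis and signalling, 25 fell in Williams and 21 in PI459025B at 216 hai, and 0 rose (25 and 23 lower adjusted over the list alone, with 1 higher in Williams). Among those that fell were probe sets of lipoxygenases, enzymes that oxidise fatty acids, such as LOX1.4 (-4.89 ± 0.61 in Williams and, at another probe set, -3.01 ± 0.61 in PI459025B). The list admits any gene whose symbol is LOX and a number, whatever its role. Its fall is therefore not by itself a fall of jasmonate synthesis or signalling. Camera gave an adjusted p = 5.05e-12 and 2.42e-06 (adjusted p = 0.0917 and 0.242 with an estimated correlation). Isoflavonoid probe sets were higher at 36 of 56 and lower at 5 in PI459025B, against 9 and 3 in Williams (37 and 5, and 9 and 3, adjusted over the list alone; camera adjusted p = 1.82e-15 and 0.0757; adjusted p = 0.0604 and 0.702 with an estimated correlation). All 7 probe sets for pathogenesis-related proteins, of 4 genes, rose in PI459025B, also when adjusted over the list alone (camera adjusted p = 2.38e-09, and 0.0352 with an estimated correlation). In Williams 4 of the 7 rose, or 5 adjusted over the list alone (camera adjusted p = 0.00239; adjusted p = 0.273 with an estimated correlation; adjusted p = 0.068 without the high-control arrays and 0.207 with array weights).

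The calls at 216 hai numbered 9515 in Williams, 3927 higher and 5588 lower, and 9813 in PI459025B, 4003 higher and 5810 lower. With median centring Williams had 5060 higher and 4274 lower. The Williams group holds the array with the hybridization-control mean of 11550, and its count was 9161 without the high-control arrays, 4194 with array weights and 2490 with only the arrays compared. In inoculated against mock leaves at 216 hai the hybridization controls were higher by 0.97 ± 0.31 on the log2 scale in Williams and 0.07 ± 0.31 in PI459025B. The mean log2 3' ratio of actin and GAPDH, which rises as RNA degrades, was higher by 0.73 ± 0.30 in Williams and differed by -0.01 ± 0.30 in PI459025B. Both Williams values rest on inoculated replicate 3, without which they were 0.17 ± 0.23 for the controls and -0.03 ± 0.22 for the 3' ratio. They were also higher without inoculated replicate 1, at 1.5 ± 0.30 and 1.23 ± 0.29. Without the high-control arrays the jasmonate list was still lower in Williams (median -3.48, camera adjusted p = 9.19e-12) at the preset correlation. With an estimated correlation and all arrays it did not pass (adjusted p = 0.0917).

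At 288 hai, ICL1 stayed high in Williams (7.43 ± 1.11, adjusted p = 2.02e-07), at a signal of 31810 ± 7067, and in PI459025B (5.48 ± 1.11, adjusted p = 0.000265), at 17330 ± 875. GLYI-19, a glyoxalase gene, rose by 7.17 ± 0.68 in Williams and 7.24 ± 0.68 in PI459025B, with all 3 mock arrays at or below the background threshold in each genotype. PGIP rose by 6.42 ± 0.51 and 5.82 ± 0.51, and OLPa by 6.05 ± 0.76 in PI459025B. The lipoxygenase genes LOXB1 (-7.02 ± 0.86), LOX9 (-6.18 ± 0.93) and VLXB (-5.94 ± 0.75) fell in Williams. A probe set of LOXB1 (-3.14 ± 0.94), CYP72A67 (-2.61 ± 0.63) and MYB138 (-2.61 ± 0.66) fell in PI459025B. The LOXB1 change in PI459025B was -2.78 without the high-control arrays, with a limma adjusted p = 0.0584. Its call was also lost without mock replicate 1 (adjusted p = 0.0786), mock replicate 2 (0.0799) or inoculated replicate 2 (0.064), and that of MYB138 without mock replicate 3 (0.0596).

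All 10 ribosomal protein probe sets, of 4 genes, fell in Williams at 288 hai, also when adjusted over the list alone. RPS6 was at -1.97 ± 0.23 and RPS13 at -1.75 ± 0.23 (camera adjusted p = 8.49e-06 for the list, and 0.14 with an estimated correlation). In PI459025B 4 probe sets fell, and 5 adjusted over the list alone (camera adjusted p = 0.0165, and 0.457 with an estimated correlation). Jasmonate probe sets were lower at 24 of 36 and higher at 3 in Williams, and lower at 6 and higher at 1 in PI459025B (24 and 3, and 7 and 1, adjusted over the list alone; camera adjusted p = 7.05e-05 and 0.101; adjusted p = 0.327 and 0.705 with an estimated correlation). Photosynthesis probe sets, of 3 genes, fell at 5 of 11 in Williams (10 adjusted over the list alone), the antenna gene LHCP by 2.37 ± 0.47 on the log2 scale. Camera gave the list an adjusted p = 0.0161 in Williams (0.403 with an estimated correlation, 0.116 without the high-control arrays and 0.0768 with array weights). In PI459025B 0 photosynthesis probe sets fell either way (camera adjusted p = 0.716). Receptor-like kinases rose at 3 of 6 probe sets in Williams, also adjusted over the list alone, RLK3 by 3.52 ± 0.44 and RLK1 by 3.00 ± 0.38 (camera adjusted p = 0.0331; adjusted p = 0.227 with an estimated correlation; adjusted p = 0.0701 without the high-control arrays), and at 0 in PI459025B either way (camera adjusted p = 0.817). The hybridization controls were higher in inoculated than mock leaves of each line, by 1.06 ± 0.31 on the log2 scale in Williams and by 0.84 ± 0.31 in PI459025B. Without inoculated replicate 2 of PI459025B the latter was 0.48 ± 0.33.

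The calls at 288 hai numbered 15533 in Williams, 5923 higher and 9610 lower, and 6385 in PI459025B, 2546 higher and 3839 lower. The median of all probe sets was -0.13 in Williams and -0.18 in PI459025B, and with median centring the splits were 9138 higher and 6519 lower and 3227 higher and 1675 lower, so the majority of lower calls depends on the scaling. With quantile normalization PI459025B had 2819 higher and 2815 lower. With only the arrays compared the counts were 9155 and 2613, and the PI459025B count was 3843 without mock replicate 3.

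**Figure D2:**
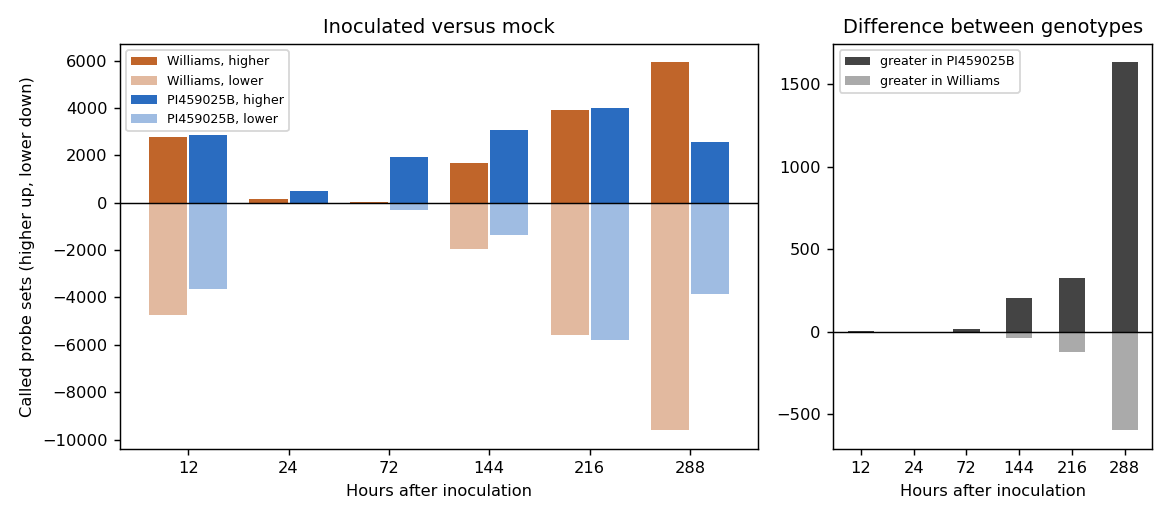
Number of called probe sets at each time, higher upward and lower downward, for inoculated against mock leaves of each genotype (left) and for the difference of the response between genotypes (right). On the right, upward is a positive difference, PI459025B minus Williams, which includes smaller falls in PI459025B. Williams has 56 calls at 72 hai and 15533 at 288 hai, against 2209 and 6385 in PI459025B.

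**Figure D3:**
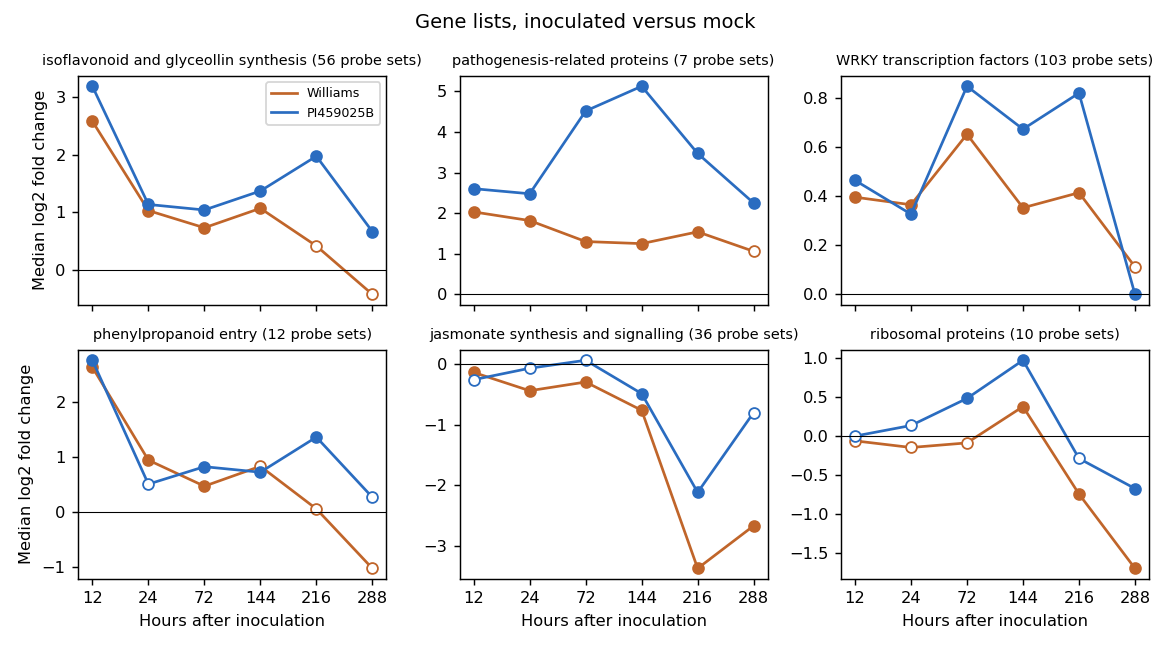
Median log2 fold change of 6 gene lists in inoculated against mock leaves by time and genotype, with filled points where camera's adjusted p was under 0.05 at its preset correlation. The isoflavonoid median is 2.58 in Williams and 3.19 in PI459025B at 12 hai, and the ribosomal protein median is -1.70 in Williams at 288 hai.

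The responses of the genotypes, which share no arrays, were set side by side. At 12 hai, 2171 probe sets were higher in both genotypes, including CYP93A1 and iomt2, where independent lists would share 219, and 2519 were lower in both, including MYB139, against 474. In opposite directions limma called 0. At 24 hai 129 were higher in both against 2.10 for independent lists, and at 72 hai 34 against 2.22. At 144, 216 and 288 hai, 886, 2022 and 2071 were higher in both, and 489, 3324 and 2880 lower, with 5, 32 and 36 called in opposite directions. The correlation of log2 fold changes across probe sets, which are not independent replicates, was 0.86, 0.58, 0.49, 0.57, 0.73 and 0.74 at 12, 24, 72, 144, 216 and 288 hai.

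The difference of the response between genotypes, PI459025B minus Williams, was tested directly, since the series title names a resistance response and only 1 of the lines is known as a source of the locus. At 72 hai, the response of a PR-10 probe set was larger in PI459025B by 4.73 ± 0.90 (adjusted p = 0.0246) and that of WRKY21 by 3.82 ± 0.81 (adjusted p = 0.0465). WRKY21 was at 8.75 ± 6.81 in PI459025B mock leaves and 640 ± 102 in inoculated ones, against 568 ± 225 and 1191 ± 666 in Williams, so its larger response started from a lower mock signal. All 3 PI459025B mock arrays were at or below the background threshold for WRKY21, so the sizes of its response and of the difference depend on the pseudocount. The PR-10 probe set was at 43.6 ± 39.5 in mock and 3940 ± 756 in inoculated leaves of PI459025B, against 2144 ± 2618 and 4070 ± 2028 in Williams, so it too started from a lower mock signal, with 2 of the 3 PI459025B mock arrays at or below the threshold. Its call was lost with a pseudocount of 64 (adjusted p = 0.0523) and with only the arrays compared (adjusted p = 0.144). With quantile normalization the WRKY21 call was lost (adjusted p = 0.0517), as with pseudocounts of 1 (0.073) and 64 (0.118), with median centring (0.0663) and with only the arrays compared (0.0506). Leaving out 1 of the 12 arrays ended the PR-10 call in 7 cases, namely Williams mock replicate 2 or inoculated replicate 3, PI459025B mock replicates 2 or 3 and each inoculated PI459025B replicate (adjusted p from 0.0517 to 0.216). It ended the WRKY21 call in 10 cases, each array but replicate 1 of mock and of inoculated Williams (adjusted p from 0.0544 to 0.263). The pathogenesis-related list had a larger response in PI459025B, with a median difference of 3.37, although only 1 of its 7 probe sets passed alone and 6 did so adjusted over the list alone (camera adjusted p = 7.52e-13; adjusted p = 0.00969 with an estimated correlation). A lower mock signal in PI459025B was seen for its member PR1-7 too, at 712 ± 1197 over all times against 3689 ± 2973 in Williams. Without Williams mock replicate 2 the PR-10 difference was 3.73, and the list was not tested with 1 array left out.

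At 144 hai, the response was higher in PI459025B than in Williams for WRKY21 (4.33 ± 0.81) and PR10 (4.22 ± 0.91). It was lower for ICL1, at another probe set than the one named above (-4.39 ± 1.13, limma adjusted p = 0.0452), and CYP83E8 (-2.76 ± 0.62). ICL1 lost its call with median centring (adjusted p = 0.0509), quantile normalization (0.0539) and a pseudocount of 1 (0.0765), and with the replicate block (adjusted p = 0.0526). Leaving out 1 of the 12 arrays ended it in 10 cases, each array but Williams mock replicate 3 and inoculated replicate 1 (adjusted p from 0.0626 to 0.161). The CYP83E8 call was lost without Williams mock replicate 1 (adjusted p = 0.0738) or PI459025B mock replicate 1 (0.0756). For WRKY21, 2 of the 3 PI459025B mock arrays were at or below the background threshold. Its signal was 18.8 ± 21.8 in mock and 894 ± 326 in inoculated PI459025B leaves, against 921 ± 205 and 1333 ± 360 in Williams. That of PR10 was 64.4 ± 22.7 and 2824 ± 797, against 2323 ± 1014 and 4224 ± 1343. Both larger responses thus started from a lower mock signal and did not reach a higher mean signal than in Williams. At 216 hai, it was higher in PI459025B for CYP81E11, on the isoflavonoid list (4.99 ± 0.97), and PR1-1 (4.53 ± 0.74, adjusted p = 0.000428), and lower for RLK3 (-3.36 ± 0.63) and GSTU47 (-2.38 ± 0.56). With only the arrays compared, CYP81E11 had an adjusted p = 0.105. The GSTU47 call was lost without Williams mock replicate 3 (adjusted p = 0.0517), Williams inoculated replicate 3 (0.055) or PI459025B inoculated replicate 2 (0.0667). PR1-1 reached 2515 ± 314 in inoculated PI459025B leaves and 167 ± 108 in inoculated Williams leaves. Of 56 isoflavonoid probe sets, 12 had a higher response in PI459025B and 0 a lower one, or 25 adjusted over the list alone (camera adjusted p = 2.48e-16; adjusted p = 0.052 with an estimated correlation). The 3' ratio differed in this contrast by -0.74 ± 0.42, or 0.02 ± 0.30 without Williams inoculated replicate 3. Without the high-control arrays, of which that is the only one at 216 hai, the list's median difference was 1.615, against 1.496 with all arrays. At 288 hai, it was higher in PI459025B for LOXB1 (6.04 ± 1.22) and VLXB (5.45 ± 1.02), and lower for RLK3 (-3.98 ± 0.63) and HPS (-2.83 ± 0.55). For LOXB1 and VLXB the mean signal fell in both lines, and by less in PI459025B. LOXB1 went from 13900 ± 9057 to 6261 ± 3617 there, against 15260 ± 5489 to 469 ± 780 in Williams. VLXB went from 12810 ± 9354 to 6903 ± 1701, against 18360 ± 2321 to 1106 ± 1745. This LOXB1 probe set is not the one named above as falling in PI459025B, and this VLXB probe set is not the one named above for Williams. The LOXB1 difference was 4.40 without the high-control arrays (adjusted p = 0.0565). With only the arrays compared, the adjusted p was 0.195 for LOXB1, 0.203 for VLXB and 0.152 for HPS. HPS was at or below the background threshold in all 3 mock arrays of each genotype. The cytochrome P450 list, which shares members such as CYP81E11 with the isoflavonoid list and holds 16 probe sets read as cyclophilins, had median differences of 0.72 at 216 hai and 1.02 at 288 hai (2 higher and 0 lower, and 12 higher and 2 lower, of 70 probe sets; 14 and 1, and 21 and 2, adjusted over the list alone). Camera gave an adjusted p = 3.51e-06 and 1.96e-06 (adjusted p = 0.0498 and 0.0443 with an estimated correlation).

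Called differences between genotypes numbered 6 at 12 hai (3 higher in PI459025B), 0 at 24 hai, 15 at 72 hai (14 higher), 245 at 144 hai (206 higher), 450 at 216 hai (325 higher) and 2232 at 288 hai (1634 higher). Higher is the sign of PI459025B minus Williams, so a smaller fall in PI459025B also counts as higher. At 288 hai the log2 fold changes had an SD over probe sets of 1.24 in Williams and 0.855 in PI459025B. The slope of those in PI459025B on those in Williams was 0.511. At 24 hai, 685 probe sets had an unadjusted p under 0.05 in limma. These counts move with single arrays and settings. At 288 hai the count was 512, 1089 and 1024 without Williams inoculated replicate 1, Williams mock replicate 1 and PI459025B mock replicate 3, and 3515 and 3420 without Williams inoculated replicates 2 and 3. It was 734 without the high-control arrays and 9 with only the arrays compared, and with median centring it split into 1217 higher and 814 lower. At 216 hai it was between 170 and 280 without Williams mock replicate 1 or 3 or inoculated replicate 3, or PI459025B mock replicate 2 or inoculated replicate 2 or 3, and 1005 and 729 without Williams inoculated replicates 1 and 2. It was 82 with only the arrays compared, and 263 and 696 with pseudocounts of 1 and 64. At 144 hai it was between 122 and 160 without Williams mock replicate 3 or inoculated replicate 2, or PI459025B mock replicate 1 or 2 or inoculated replicate 2, 390 without the high-control arrays and 460 with only the arrays compared. At 72 hai it was 0 without Williams mock replicate 2 or inoculated replicate 3, PI459025B mock replicate 2 or any 1 inoculated PI459025B array, 9, 7 and 5 without Williams mock replicate 3, Williams inoculated replicate 2 and PI459025B mock replicate 3, and 84 without Williams mock replicate 1. It was 78 without the high-control arrays and 6 with quantile normalization. At 12 hai it was 2 without Williams inoculated replicate 3, 0 with only the arrays compared and 10 with a pseudocount of 64. Array weights gave 14, 98, 82 and 1644 at 12, 24, 72 and 144 hai.

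**Figure D4:**
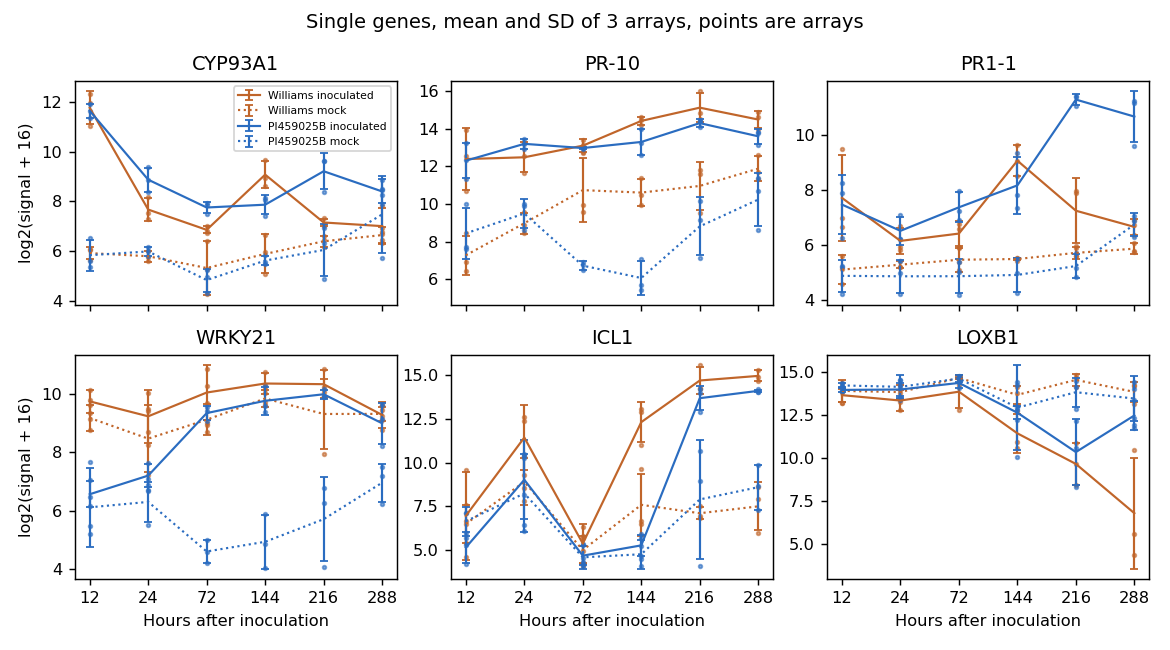
Signal of 6 genes, as log2(signal + 16), against time in inoculated and mock leaves of both genotypes, with the mean and SD of 3 arrays and a point per array. Inoculated and mock PI459025B leaves stand apart at 72 hai for PR-10 (8025 against 90.9) and WRKY21 (640 against 8.75).

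In mock leaves, the genotypes differed at 8305 probe sets, 4027 higher and 4278 lower in PI459025B, each from 18 arrays against 18. Among genes with a symbol or synonym that is not a placeholder, the largest difference was at KNBS1, with 1 probe set lower by 5.03 ± 0.15 on the log2 scale (-5.03, adjusted p = 1.96e-33) and another higher by 2.86 ± 0.17; of its 6 probe sets 4 were lower and 1 higher. The first was at or below the background threshold in all 18 PI459025B mock arrays, so its size depends on the pseudocount. WRKY21 (-3.44 ± 0.23), SIK2 (-3.43 ± 0.23), SEOS (-3.13 ± 0.48), PR1-7 (-3.08 ± 0.25) and SIP1-3 (-2.97 ± 0.17) were lower in PI459025B, as were the lipoxygenase genes LOX7 (-2.53 ± 0.40) and LOX9 (-2.32 ± 0.30), SIP1-4 (-2.46 ± 0.17) and H4 (-2.33 ± 0.32). Higher were AG1 (2.78 ± 0.30), FT1A (2.64 ± 0.22), CYP76O2 (2.39 ± 0.32), PAP25 (1.79 ± 0.32), H-1 (1.67 ± 0.39), COI1 (1.41 ± 0.21), GSTL1 (1.26 ± 0.26) and GA2OX6 (1.19 ± 0.30). AG1 was at or below the threshold in 13 of 18 Williams and 4 of 18 PI459025B mock arrays, GSTL1 in 14 and 7, and GA2OX6 in 10 and 4. WRKY21 was so in 7 of 18 PI459025B mock arrays. The sizes of these 4 differences depend on the pseudocount too. SFERH-2 was higher at 1 probe set (1.82 ± 0.46) and lower at another. A probe set compares the genotypes only as far as its probes match both, and 209 probe sets were over 4-fold lower in PI459025B against 52 over 4-fold higher.

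Under the naming rule as first written, which counts placeholder symbols, the largest changes were often at genes with no other name. LOC100815336 rose at 12 hai by 6.47 ± 0.51 in Williams and 6.60 ± 0.51 in PI459025B, with all 3 mock arrays of each genotype at or below the background threshold. LOC100500657 rose in PI459025B by 5.20 ± 0.69 at 24 hai and 6.78 ± 0.69 at 72 hai, where its response was also higher than in Williams (4.77 ± 0.98, limma adjusted p = 0.0286). That difference was not called with quantile normalization (adjusted p = 0.0517), pseudocounts of 1 (0.0528) or 64 (0.0523) or only the arrays compared (0.069). Leaving out 1 of the 12 arrays ended it in 9 cases, each array but Williams mock replicates 1 and 3 and inoculated replicate 1 (adjusted p from 0.0532 to 0.319). LOC100306379 rose in Williams by 8.52 ± 0.49 at 216 hai and 9.12 ± 0.49 at 288 hai, and LOC100777055 in PI459025B by 8.21 ± 0.65 at 288 hai. All 3 Williams mock arrays for LOC100306379 at each of these times, and 2 of 3 PI459025B mock arrays for LOC100777055, were at or below the background threshold. The sizes of these changes, and of that of LOC100815336, depend on the pseudocount. In mock leaves LOC100306601 was lower in PI459025B (-5.13 ± 0.14). Of 3 probe sets of LOC100527213, 1 was higher in PI459025B (5.80 ± 0.28) and 2 were lower.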

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

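The tests of the high-control arrays, of array quality with arrays left out, of RNA degradation, of a single odd array and of the other splits, and the contrasts between consecutive times, were chosen only after the results were seen; those of sequence differences and of an equal response hidden by spread were not.

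Results are listed here because the response differed between genotypes or times in a direct test, or because a signal appeared in the hybridization controls. The response differed between genotypes at 6, 15, 245, 450 and 2232 probe sets at 12, 72, 144, 216 and 288 hai. The single genes were PR-10 (4.73) and WRKY21 (3.82) at 72 hai, WRKY21 (4.33), PR10 (4.22), ICL1 (-4.39) and CYP83E8 (-2.76) at 144 hai, CYP81E11 (4.99), PR1-1 (4.53), RLK3 (-3.36) and GSTU47 (-2.38) at 216 hai, and LOXB1 (6.04), VLXB (5.45), RLK3 (-3.98) and HPS (-2.83) at 288 hai. The lists were pathogenesis-related proteins at 72 hai (median 3.37) and cytochrome P450 at 216 hai (0.72) and 288 hai (1.02). Within Williams, the response differed between 12 and 24 hai at 1104 probe sets, between 72 and 144 hai at 11, between 144 and 216 hai at 1688 and between 216 and 288 hai at 1428. Within PI459025B, it differed between 12 and 24 hai at 1105, between 24 and 72 hai at 1, between 144 and 216 hai at 2046 and between 216 and 288 hai at 49. The hybridization controls were higher in inoculated than mock leaves by 0.97 log2 units in Williams at 216 hai, 1.06 in Williams at 288 hai and 0.84 in PI459025B at 288 hai. The first was 0.17 without inoculated replicate 3 and 1.5 without inoculated replicate 1, and the last was 0.48 without inoculated replicate 2.

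More probe sets were called in Williams (15533) than in PI459025B (6385) at 288 hai. Without the high-control arrays the counts were 12452 and 7218. With these or any 1 array left out, the Williams count was at least 11154 and the PI459025B count at most 7218, which argues against these arrays as the whole source of the excess in Williams. The inoculated Williams arrays that stayed in had control means of 3585 and 2311, against 2146 and 1952 in PI459025B. A part of the difference in the controls thus remained, and its effect was not tested. The count of different responses at 288 hai is another matter. It fell from 2232 to 734 without them, neither to 0.1 of it nor within 1.5 times, so for that count these arrays as a source cannot be told apart from a difference between the lines. The mean log2 3' ratio of actin and GAPDH rose by 0.44 ± 0.30 in Williams and 0.47 ± 0.30 in PI459025B, a difference, Williams minus PI459025B, of -0.03 (SE 0.42), which leaves degraded RNA open. Without Williams inoculated replicate 1 the first was 0.27, and without PI459025B inoculated replicate 2 the second was 0.13. A difference in response between the lines stays open as well.

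The genotypes differed at 8305 probe sets in mock leaves. If sequence differences under the probes were the source, probe sets of 1 gene should part more often than in a comparison within a genotype. Of 156 genes with a 2-fold call, 37.18% (exact interval 29.59 to 45.27) had another probe set over 1 log2 unit away, against 43.22% (39.2 to 47.3) of 597 genes in Williams at 216 hai, the reference set beforehand, whose group holds the array with high 3' ratios. In the other comparisons within a genotype the share ran from 27.61% (23.14 to 32.45) in PI459025B and 30.73% (26.37 to 35.37) in Williams at 12 hai to 45.45% (24.39 to 67.79) in Williams at 24 hai, on either side of that in mock leaves. The prediction written beforehand took a share at or below the reference as speaking against sequence differences, and the share met it. The overlap of the intervals was used here instead, and by it sequence differences and differences in mRNA cannot be told apart. Probe sets called in opposite directions were found for 7 of the 156 genes, against 9 of 597 in Williams at 216 hai and 22 of 931 at 288 hai. Other comparisons within a genotype had 0 to 4 such genes. This was not among the predictions. In mock leaves 209 probe sets were over 4-fold lower in PI459025B against 52 higher.

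Fewer probe sets were called in Williams (56) than in PI459025B (2209) at 72 hai. Over the 2171 probe sets called higher in both genotypes at 12 hai, the mean response at 72 hai was higher in PI459025B by 0.44 (SE 0.21), over the 0.1 of an equal response but by less than 2 standard errors beyond it. Without Williams mock replicate 2 it was 0.27 (SE 0.21). Leaving out Williams mock replicate 2 raised the Williams count to 281, neither below 0.1 of 2209 nor within 1.5 times of it. Array spread, a single odd array and a smaller response in Williams therefore cannot be told apart.

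For each response, the 6 arrays make 10 splits, too few for a share under 0.05. The real and highest other counts were, for Williams, 7499 and 99 at 12 hai, 162 and 3 at 24 hai, 56 and 148 at 72 hai, 3599 and 0 at 144 hai, 9515 and 6646 at 216 hai, and 15533 and 1391 at 288 hai. For PI459025B they were 6519 and 54, 495 and 2, 2209 and 51, 4462 and 3, 9813 and 53, and 6385 and 753. In PI459025B at 72 hai, where arrays with the same replicate number deviated together in all 3 pairs, no other split gave more than 51, whether or not it parted as many pairs. At 72 hai in Williams 2 of the 10 splits gave as many, and 1, the real one, in each other case. For mock leaves the count was 8305 against a highest other of 683 (1 of 100 splits, the real one). Single arrays were redrawn, so chance can be excluded there only as far as the arrays of a group are independent. The labels do not say whether they came from separate plants.

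For the difference between genotypes, labels were first redrawn within each genotype. As many calls came from 24, 100, 15, 15, 27 and 14 of 100 splits at 12, 24, 72, 144, 216 and 288 hai, with highest others of 12459, 429, 1869, 8172, 10003 and 12382 against real counts of 6, 0, 15, 245, 450 and 2232. The others lie far above the real counts because a split that swaps the labels of 1 genotype carries the inoculation response into the contrast, a structure of the samples, so this form says nothing about chance. A second form, chosen after that result was seen, redrew the 12 arrays once additive effects of genotype and inoculation were removed. In it 1, 3, 1, 6 and 1 of 100 gave as many at 12, 72, 144, 216 and 288 hai, with highest others of 5, 22, 15, 3017 and 2005. With all arrays the share was under 0.05 at 12, 72, 144 and 288 hai, and not at 216 hai. Removing additive effects shrinks the redrawn contrasts but not the real one, so this form favours the real labels and cannot by itself exclude chance. The margin was narrow at 12 hai (6 against 5) and 288 hai (2232 against 2005) and wide at 144 hai (245 against 15). The counts at 12 and 288 hai also fell with only the arrays compared. At 72 hai the shared deviations of PI459025B arrays with the same replicate number were ignored. The highest other there (22) exceeded the real count (15). At 24 hai limma called 0 (685 at an unadjusted p under 0.05), so 100 of 100 splits gave as many by construction (highest other 2), and this says nothing about chance. The splits were not redrawn with arrays left out, and the real counts move with single arrays, so the shares of splits hold only for the full set. At 12 hai the count was 2 without Williams inoculated replicate 3. At 72 hai it was 0 without Williams mock replicate 2 or inoculated replicate 3, PI459025B mock replicate 2 or any 1 inoculated PI459025B array, 9, 7 and 5 without Williams mock replicate 3, Williams inoculated replicate 2 and PI459025B mock replicate 3, and 84 without Williams mock replicate 1. At 144 hai it was between 122 and 160 without Williams mock replicate 3 or inoculated replicate 2, or PI459025B mock replicate 1 or 2 or inoculated replicate 2. At 288 hai it was 512, 1089 and 1024 without Williams inoculated replicate 1, Williams mock replicate 1 and PI459025B mock replicate 3, and 3515 and 3420 without Williams inoculated replicates 2 and 3, and 734 without the high-control arrays.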

How the results depend on the processing

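The fit without the high-control arrays and the lists without misnamed members were chosen only after the results were seen. The 19 counts of called probe sets stayed within 1.5 times with no filter, with a filter at 12 arrays, with trended and robust eBayes and with the replicate block. With quantile normalization the difference between genotypes at 72 hai was 6, and with median centring Williams at 72 hai was 29. A pseudocount of 1 gave 34 for Williams at 72 hai and 263 for the difference at 216 hai. A pseudocount of 64 gave 87 for Williams at 72 hai and 10 and 696 for the difference at 12 and 216 hai. With only the arrays compared, which leaves fewer residual degrees of freedom, Williams was 49 at 24 hai, 0 at 72 hai, 2490 at 216 hai and 9155 at 288 hai, PI459025B was 2613 at 288 hai, and the difference was 0 at 12 hai, 1 at 24 hai, 460 at 144 hai, 82 at 216 hai and 9 at 288 hai. Array weights, whose estimation stopped before it converged, gave Williams 12160, 1564, 419, 10223 and 4194 at 12, 24, 72, 144 and 216 hai, PI459025B 11011, 4117, 4648, 7932, 15069 and 10412 at the 6 times, the difference 14, 98, 82 and 1644 at 12, 24, 72 and 144 hai, and mock leaves 12563. Without the high-control arrays Williams was 169 at 72 hai and 5415 at 144 hai, and the difference was 1, 78, 390 and 734 at 24, 72, 144 and 288 hai. With 1 array left out, Williams ranged from 4868 (without inoculated replicate 3) to 7110 at 12 hai, 8 (inoculated 2) to 162 at 24 hai, with 22 without mock 2, 1 (inoculated 1) to 281 (mock 2) at 72 hai, with 5, 17, 14 and 148 without mock 1, mock 3, inoculated 2 and inoculated 3, 2108 (inoculated 3) to 2940 at 144 hai, with 2157 and 2144 without mock 2 and inoculated 2, 6749 to 10754 at 216 hai, and 11154 to 15628 at 288 hai. PI459025B ranged from 4389 to 5469 at 12 hai, 250 (inoculated 2) to 432 at 24 hai, with 310 and 276 without mock 1 and mock 2, 1448 (inoculated 2) to 1934 at 72 hai, 2648 (inoculated 2) to 3766 at 144 hai, with 2874 without mock 2, 7030 to 10126 at 216 hai, and 3843 (mock 3) to 5442 at 288 hai. The difference ranged from 2 (Williams inoculated 3) to 8 at 12 hai, 0 to 1 (Williams mock 3, PI459025B mock 3) at 24 hai, 0 (Williams mock 2 and inoculated 3, PI459025B mock 2 and all 3 inoculated) to 84 (Williams mock 1) at 72 hai, with 9, 7 and 5 without Williams mock 3, Williams inoculated 2 and PI459025B mock 3, 122 (PI459025B inoculated 2) to 309 at 144 hai, with 131, 160, 140 and 136 without Williams mock 3, Williams inoculated 2, PI459025B mock 1 and PI459025B mock 2, 170 (PI459025B inoculated 2) to 1005 (Williams inoculated 1) at 216 hai, with 214, 177, 729, 215, 209 and 280 without Williams mock 1, mock 3, inoculated 2 and inoculated 3 and PI459025B mock 2 and inoculated 3, and 512 (Williams inoculated 1) to 3515 (Williams inoculated 2) at 288 hai, with 1089, 3420 and 1024 without Williams mock 1, Williams inoculated 3 and PI459025B mock 3. Mock leaves ranged from 7354 to 8852. The cause of these moves was not tested. The labels do not say what a replicate number marks. Deviations of arrays with the same number correlated at 0.033 on average, against -0.016 for other numbers, and 1 of 12 comparisons, PI459025B at 72 hai, had all 3 pairs over 0.1 (0.225, 0.159 and 0.433). The replicate block gave Williams 7690, 158, 64, 3759, 9751 and 15797, PI459025B 6674, 508, 2289, 4631, 9997 and 6617, the difference 6, 0, 19, 238, 475 and 2410, and mock leaves 8550, and of the genes named it ended only the call of ICL1 at 144 hai. The jasmonate list's difference at 216 hai reversed with array weights (median -0.27, adjusted p = 0.784), and the cause was not tested. Of the list calls, 7 were lost with quantile normalization, 7 with median centring, 6 and 2 with pseudocounts of 1 and 64, 8 without the high-control arrays and 14 with array weights. Without misnamed members 1 call was lost, that of the cytochrome P450 list for the difference at 144 hai (camera adjusted p = 0.0875). The calls of that list for the difference at 216 and 288 hai were kept. The lists were not tested with 1 array left out or with only the arrays compared. Signals near background limit 13 of the 111 response changes, of 72 genes, that the naming rule picked, since all 3 arrays of the lower group were at or below the background threshold: 6 of 67 under symbols that are not placeholders and 10 of 69 under any symbol, some picked under both.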

Other observations

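The tests that follow genes called at 12 hai over time, and those with arrays left out, were chosen only after the results were seen. Among sugar transport genes, STP1, a monosaccharide transporter, rose at 12 hai by 2.66 ± 0.38 in Williams and 3.96 ± 0.38 in PI459025B, while SWEET42, of the sugar exporter family, fell (-1.08 ± 0.22 and -0.83 ± 0.22). Of the list's 14 probe sets, 2 rose and 2 fell in Williams and 2 rose and 1 fell in PI459025B at that time, also adjusted over the list alone (limma camera adjusted p = 0.692 and 0.549; adjusted p = 0.803 and 0.722 with an estimated correlation). SWEET29 rose at 288 hai by 4.18 ± 0.49 in Williams and 3.73 ± 0.49 in PI459025B. Of the 14 probe sets, 5 rose and 2 fell in Williams and 3 rose and 1 fell in PI459025B at 288 hai (5 and 2, and 6 and 1, adjusted over the list alone), with a limma camera adjusted p = 0.0619 and 0.00385 (adjusted p = 0.233 and 0.0737 with an estimated correlation). ACS1, an enzyme of ethylene synthesis, rose at 12 hai by 2.84 ± 0.43 in Williams and, at another probe set, by 3.06 ± 0.40 in PI459025B, and of the 11 probe sets of its list 3 rose in each genotype, also adjusted over the list alone (camera adjusted p = 0.0227 and 0.00775; adjusted p = 0.267 and 0.186 with an estimated correlation).

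Of 17 probe sets on the list for senescence and nitrogen remobilisation, 5 fell in Williams at 216 hai, also adjusted over the list alone, with LOXB1 at -5.77 ± 0.94 and the vegetative storage protein VSPA at -0.83 ± 0.30 (limma camera adjusted p = 0.00385; adjusted p = 0.411 with an estimated correlation; adjusted p = 0.104 with array weights). In PI459025B 4 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.123). Of 7 peroxidase probe sets 3 rose at 12 hai in each genotype, or 3 adjusted over the list alone with 2 lower in PI459025B, and PRX4 rose by 4.17 ± 0.68 in Williams and 5.25 ± 0.68 in PI459025B (camera adjusted p = 0.0373 and 0.0128; adjusted p = 0.231 and 0.148 with an estimated correlation). The Williams list call was lost with quantile normalization (adjusted p = 0.0513), median centring (0.0767), a pseudocount of 1 (0.0726), array weights (0.0512) and without the high-control arrays (0.0502). At 24 hai in PI459025B the peroxidase list's median was -0.09 and its mean 1.28, and camera gave the higher direction (adjusted p = 0.014; adjusted p = 0.152 with an estimated correlation; adjusted p = 0.061 with a pseudocount of 1 and 0.0898 with array weights). In Williams they were 0.26 and 1.11 (adjusted p = 0.00976; adjusted p = 0.14 with an estimated correlation; adjusted p = 0.136 with array weights). The jasmonate list at 12 hai in Williams had a median of -0.13, a mean of 0.13 and the higher direction in camera (adjusted p = 0.0178; adjusted p = 0.59 with an estimated correlation; adjusted p = 0.0545 with quantile normalization and 0.0965 with median centring), and in PI459025B camera gave an adjusted p = 0.0895. The cytochrome P450 list at 12 hai in PI459025B had a median of -0.03, a mean of 1.09 and the higher direction (adjusted p = 9.12e-09; adjusted p = 0.0176 with an estimated correlation), and in Williams 0.05 and 0.85 (adjusted p = 1.35e-07; adjusted p = 0.0297 with an estimated correlation). The root and nodule list had 0 of 9 probe sets higher and 2 lower at 12 hai in Williams (limma camera adjusted p = 0.649), with 0 and 2 adjusted over the list alone, and 0 of either in PI459025B (camera adjusted p = 0.43), also adjusted over the list alone.

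The 2171 probe sets called higher in both genotypes at 12 hai had a mean response of 2.06 in Williams and 2.22 in PI459025B at that time (SE 0.15). These values are raised by the choice of the set at 12 hai. At 24, 72, 144, 216 and 288 hai the mean was 0.65, 0.52, 0.87, 0.90 and 0.70 in Williams and 0.75, 0.97, 1.09, 1.58 and 0.91 in PI459025B. At 216 hai the response of the set was higher in PI459025B by 0.67 (SE 0.21). The 3' ratio differed in that contrast by -0.74 (SE 0.42), through Williams inoculated replicate 3, without which the differences were 0.60 (SE 0.22) for the set and 0.02 (SE 0.30) for the 3' ratio.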
